A study of Homo sapiens with 12 samples.

How the data were processed

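Gene expression was measured on Illumina bead arrays, with 1 array for each of 12 samples of cultured human stromal cells, 6 established from normal endometrium and 6 from ovarian endometriomas. Samples were grouped by the tissue named in the labels, and replicate numbers were taken from the same labels. The labels do not say whether samples of a group came from separate donors, so p-values measure the spread between these samples.

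The deposited values are on a log2-like scale. They were made by the authors with BeadStudio and the R package lumi, per the submitters' processing notes, and versions, background correction and the exact transform are not given in the sources used here. All 12 deposited columns held the same distribution of log2 values, with a lowest value of 6.52, a median of 7.07, an upper quartile of 7.58 and a highest value of 15.5, so the values were already quantile normalized between arrays. Quantile normalization removes any shift shared by all genes of an array. Low signals are compressed towards the bottom of the scale, and fold changes of dim genes are therefore understated. Detection p-values and scanner files were not used here, and the number of arrays limits the precision.

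Probes were named through the platform annotation. Of 48802 probes, 28097 had 1 gene symbol, 13 had several and 20692 had none in that table. XIST and Y-linked genes (122 probes) were left out because the donors are people. For each gene the probe with the highest mean over all arrays was used, which gave 18776 genes, of which 6099 had more than 1 probe. Among 352 genes past the threshold with more than 1 probe, only GPRC5C had a probe past the threshold in the opposite direction. Other probes of a called gene could miss the threshold, as for CALB2 (1 of 2 probes past it), MME (1 of 4) and CYP19A1 (1 of 4). Probes of AKR1C3, AKR1C1 and AKR1C2 can cross-hybridize between these near-identical genes, and their levels are uncertain for that reason.

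The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit with group as the only term, eBayes with an intensity trend). P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and a second count required at least a 2-fold difference. Differences are endometriotic minus normal. No gene was removed for low signal. Of 36 gene lists, 35 had at least 3 measured members and were tested with limma's camera (two-sided, preset correlation of 0.01, Benjamini-Hochberg over lists). The lists covered nuclear steroid receptors, steroidogenesis, prostaglandins, retinoids, GATA factors, the HOXA, HOXB, HOXC and HOXD clusters, Mullerian and uterine patterning, ovarian stroma and gonadal transcription factors, decidualization, estrogen-regulated genes, WNT, TGF-beta and BMP signalling, the IGF axis, collagens and matrix glycoproteins, proteoglycans, matrix proteases, cytokines, complement, interferon-stimulated genes, cell cycle, cyclin-dependent kinase inhibitors, smooth muscle, hypoxia and glycolysis, cholesterol and fatty acid synthesis, DNA methylation and Polycomb enzymes, and heat shock. Marker lists covered epithelial, endothelial, leukocyte, pericyte, mesothelial, granulosa and theca, and endometrial stroma cells. Arrays were compared by 1 minus the Pearson correlation over all genes, with exact permutation tests over the 924 splits of 12 arrays into 6 and 6.

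The rule for named genes took the 12 largest positive and the 12 largest negative log2 differences among genes past the threshold whose values did not overlap between groups, up to 4 members past the threshold per list, and 44 index genes whatever their value, of which 39 had a named probe. HOXA9, HOXA10, HOXA11 and NR2F2 were among those not analysed here. The lists, this rule, the tests and most alternatives were fixed before the data were examined. Alternatives were other between-array normalizations, a filter on dim genes, the mean of a gene's probes, array weights, the replicate number as a block, other variance models, an exact rank-sum test, limma's treat, other list tests, and leaving out each array in turn. Cyclic loess was added after seeing the data.

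The scripts were tested on simulated data for this comparison over 18776 genes, of which 200 were changed. Of the simulated 2-fold changes 88% were recovered, and of the 4-fold changes 99%, at 100 genes each. The changed genes were drawn only from those with a mean above the median of probe means. All simulated arrays of a group were shifted alike. Recovery among dim genes, or with an array that lies among the other group, was not tested. Among the calls, 10 (5.08%) were unchanged genes. The 1 shifted list was called and none of the unshifted lists was. The simulated genes varied independently of each other, so this does not test false list calls that correlated genes can give. Figures were drawn with matplotlib 3.10.9.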

Results

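The data were genome-wide expression profiles of stromal cells grown in culture from normal endometrium (6 arrays) and from ovarian endometriomas, the cysts that endometriosis forms in the ovary (6 arrays). The comparison asked how stromal cells from the lesion differ in expression from those of the normal uterine lining. Each array contributed normalized log2 signals for 18776 genes.

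Lists of retinoid genes (5 of 25 members lower), HOXB genes (3 of 10) and uterine patterning genes (5 of 17) were shifted down in endometriotic stromal cells relative to normal stromal cells. Lists of steroidogenic genes (4 of 27 members higher) and gonadal genes (4 of 17) were shifted up, each with adjusted p = 0.140 with an estimated correlation. STAR and NR5A1 were among the higher members of both lists, so these results overlap. ALDH1A1, an enzyme that makes retinoic acid, was 20.7-fold lower (log2 difference -4.37 ± 0.52, SE, 6 arrays per group), and CALB2, the calcium-binding protein calretinin, was 19.6-fold higher (4.29 ± 0.50). The other of the 2 CALB2 probes did not pass the threshold (log2 difference -0.0735). In limma with Benjamini-Hochberg adjustment, 897 genes differed, 526 of them higher and 371 lower in endometriotic stroma, and 386 of these differed at least 2-fold (234 higher, 152 lower). The values of 368 genes did not overlap between the groups, against 40.6 (0.216%) given by chance.

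Among the genes with non-overlapping values, the largest reductions after ALDH1A1 were in TMEM119 (10.3-fold lower), the retinoic acid carrier CRABP2 (8.87-fold), the matrix protein POSTN (6.13-fold) and the retinaldehyde dehydrogenase ALDH1A2 (6.13-fold, limma adjusted p = 2.7e-05). OLFML3 (5.40-fold), the protease inhibitor TFPI2 (5.05-fold), the complement protease MASP1 (4.83-fold), ISLR (4.35-fold), the stromal marker MME, also known as CD10 (4.09-fold), the growth factor MDK (3.83-fold) and MOXD1 (3.75-fold) followed. After CALB2, the largest increases were in PNCK (5.86-fold higher), the anti-Mullerian hormone receptor AMHR2 (5.75-fold), the cell adhesion protein CXADR (5.31-fold), RNASE1 (5.21-fold), ZPLD1 (4.90-fold), the kinase DAPK1 (4.73-fold), DRC9 (4.70-fold), the collagen COL8A1 (4.68-fold), cyclin D2 (CCND2, 4.48-fold), the neurotrophin BDNF (4.34-fold) and PSD3 (4.06-fold).

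Endometriotic replicate 5 stood apart from the other endometriotic arrays and lay within the range of the normal arrays on the first principal component. Its score there was -10.98, against 23.2 to 38.9 for the other 5 endometriotic arrays and -39.5 to -3.97 for the normal arrays. On the second component it stood at 31.0, above every normal array (highest 23.9), and its mean correlation with the normal arrays (0.956) was below that of each normal array with the others (0.959 to 0.971). The groups of arrays were separated, with a mean distance (1 minus Pearson correlation) of 0.0558 between and 0.0347 within groups (difference 0.0210, exact one-sided permutation p = 0.00433). The smallest p this permutation test can give is 0.00216, so another grouping of the arrays separated them at least as well as the labels. Normal replicate 2 had a mean correlation of 0.959 both with the other normal arrays and with the endometriotic arrays. Without normal replicate 2, 1310 genes differed. Array distances to the rest of the group averaged 0.0213 ± 0.0053 (SD) in normal and 0.0208 ± 0.0125 in endometriotic stroma (exact two-sided permutation p = 0.948). That comparison rested on endometriotic replicate 5 (0.0463, next 0.0168), and removing this farthest array, which itself narrows the group, gave a difference of -0.00636 (exact permutation p = 0.0260). Without endometriotic replicate 5, 1398 genes differed (796 higher, 602 lower), 587 of them at least 2-fold. This array was singled out from these same values. Leaving out an array that lies among the other group tends to widen group differences. Smaller p-values without it, here and below, are therefore no added support for a difference.

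**Figure D1:**
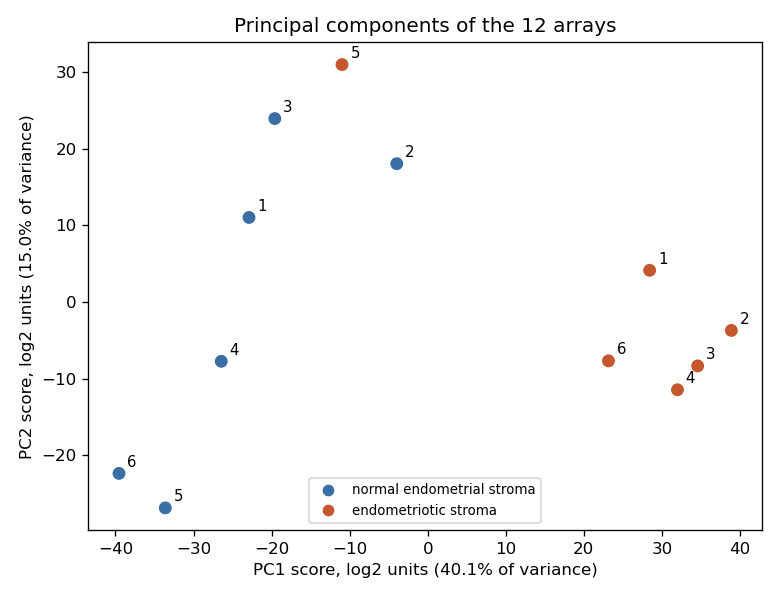
Scores of the 12 arrays on the first (40.1% of variance) and second (15.0%) principal components of the log2 signals, each point an array numbered by replicate. Endometriotic replicate 5 lies at -10.98 on the first component, inside the normal range and apart from the other endometriotic arrays at 23.2 to 38.9, and at 31.0 on the second, above every normal array.

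Of 25 measured genes of retinoid uptake, metabolism and targets, 5 were lower and none higher in endometriotic stroma (7 lower when adjusted over the list alone), and the list was shifted down (camera adjusted p = 0.000320, 0.0353 with an estimated correlation, 0.0508 on ranks). Besides ALDH1A1, CRABP2 and ALDH1A2, the lower members were the transglutaminase TGM2 (6.27-fold, or 10.2-fold without endometriotic replicate 5) and STRA6, the cellular retinol importer (2.67-fold). The receptor RARB did not pass the threshold (1.36-fold lower, limma adjusted p = 0.333). Endometriotic replicate 5 held ALDH1A1 at 11.29 and TGM2 at 13.43, against means of 8.31 and 9.19 in the other 5 endometriotic arrays.

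The HOXB cluster had 3 of 10 members lower (4 when adjusted over the list alone), namely HOXB2 (2.28-fold), HOXB7 (1.94-fold) and HOXB5 (1.54-fold), and was shifted down (camera adjusted p = 0.000183, 0.0353 with an estimated correlation). Of 17 Mullerian and uterine patterning genes, 5 were lower (7 when adjusted over the list alone; camera adjusted p = 4.3e-05, 0.0353 with an estimated correlation). These included HOXD11 (2.56-fold), MEIS1 (2.53-fold), HAND2, a progesterone-regulated factor of uterine stroma (2.32-fold), and EMX2 (2.30-fold), while WNT4 (limma adjusted p = 0.898) did not differ detectably. In the HOXD cluster only HOXD11 of 9 members was called (2 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.417), and HOXD10 was 2.87-fold lower with limma adjusted p = 0.0545, or 0.000107 without endometriotic replicate 5, which stood at 9.75 against a mean of 6.99 in the other 5. None of 9 HOXC genes was called, also when adjusted over the list alone (camera adjusted p = 0.0754). HOXC6 (2.78-fold higher, limma adjusted p = 0.148) and HOXC8 (1.97-fold, 0.165) did not pass, and both passed without endometriotic replicate 5 (limma adjusted p = 0.0230 and 0.0223). The HOXC list was called with array weights (0.0438) and without normal replicate 1 (0.0404), normal replicate 5 (0.00990) or endometriotic replicate 5 (0.0247), but had adjusted p = 0.512 with an estimated correlation over all arrays and 0.427 without endometriotic replicate 5. The HOXA list had 1 measured member, HOXA2 (1.16-fold lower, limma adjusted p = 0.287), and was not tested as a list.

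Endometrial stroma markers had 4 of 11 members lower (MME, IFITM1 at 3.26-fold, HAND2 and ECM1 at 2.29-fold; adjusted over the list alone, 5 were lower and 1 higher), with camera adjusted p = 0.000320 and adjusted p = 0.0995 with an estimated correlation.

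**Figure D2:**
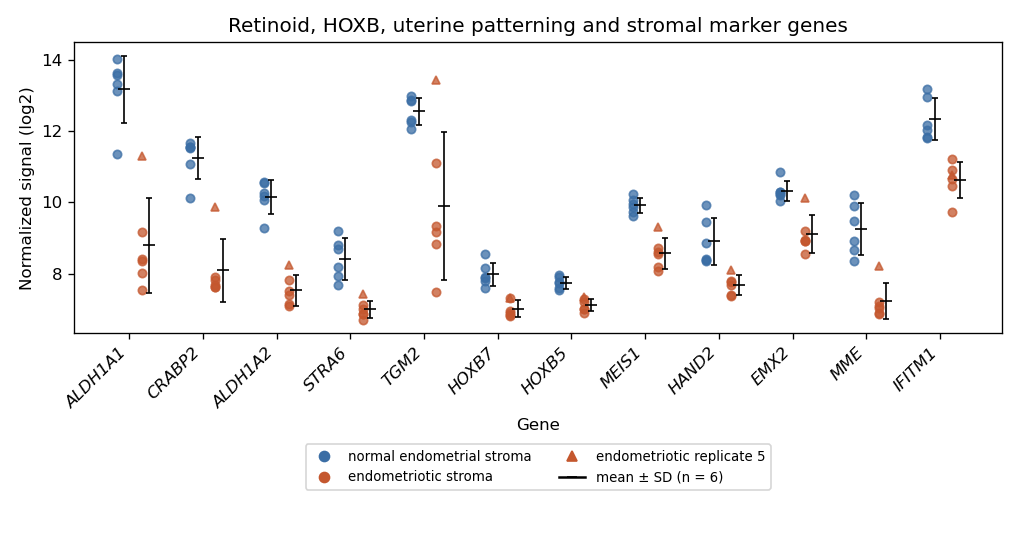
Normalized log2 signal of 12 genes lower in endometriotic stroma, with a point per array, bars for mean ± SD (6 arrays per group) and a triangle for endometriotic replicate 5. The triangle lies above the other endometriotic arrays for ALDH1A1 (11.29) and TGM2 (13.43), and ALDH1A2 separates the groups with a difference of -2.61 log2 units.

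Of 27 genes of steroidogenesis and steroid metabolism, 4 were higher and none lower (6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.00192, adjusted p = 0.140 with an estimated correlation). The cholesterol transporter STAR was 7.08-fold higher, NR5A1 (SF-1), which drives steroidogenic genes, 3.19-fold, the side-chain cleavage enzyme CYP11A1 2.83-fold and aromatase, CYP19A1, 2.16-fold. STAR stood at 6.88 in endometriotic replicate 5, near the normal mean of 6.95, against a mean of 10.35 in the other 5, and NR5A1 at 6.87 against 8.98. HSD17B2, which inactivates estradiol, was 2.58-fold lower (limma adjusted p = 0.0884, or 0.000749 without endometriotic replicate 5), AKR1C3 was 2.47-fold higher (0.283, or 4.10-fold and 0.000610 without it), and HSD17B1 was 1.59-fold higher (0.181, or 0.0818 without it).

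Ovarian stroma and gonadal transcription factors had 4 of 17 members higher (7 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.00878, adjusted p = 0.140 with an estimated correlation), namely STAR, AMHR2, NR5A1 and GATA4. The list's call was lost without normal replicate 2 (camera adjusted p = 0.0580). GATA4, a gonadal GATA factor, was 2.47-fold higher and GATA2, which uterine stroma uses, 2.81-fold lower. The GATA list also held ZFPM2 at 2.01-fold higher (2 of 8 higher and 1 lower; 3 and 2 when adjusted over the list alone; camera adjusted p = 0.432). GATA6 (1.47-fold higher, limma adjusted p = 0.0704) and TCF21 (2.07-fold, 0.0617) did not pass, and both passed without endometriotic replicate 5 (limma adjusted p = 0.00318 and 0.00126) and with array weights (0.0164 and 0.0125). With every probe tested on its own, 1 of the 3 TCF21 probes passed. In endometriotic replicate 5, GATA2 stood at 9.34 against a mean of 7.12 in the other 5. WT1 did not differ detectably (limma adjusted p = 0.972).

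Mesothelial markers had 2 of 10 members higher, CALB2 and ITLN1 (3.18-fold; 3 when adjusted over the list alone; camera adjusted p = 0.00153, adjusted p = 0.0995 with an estimated correlation). Granulosa and theca markers had CYP11A1 and INHA (1.30-fold) higher of 10 (3 when adjusted over the list alone; camera adjusted p = 0.291). CALB2 stood at 10.55 in endometriotic replicate 5 and at a mean of 13.30 in the other 5.

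The IGF axis had 4 of 18 members higher and 1 lower (5 and 1 when adjusted over the list alone). Its camera call (adjusted p = 0.0472) was lost without normal replicate 1 (0.0590), 3 (0.0575), 4 (just above 0.05) or 6 (0.0551) and without endometriotic replicate 1 (0.0570), 2 (0.0740) or 5 (0.0873), and it had adjusted p = 0.140 with an estimated correlation. The binding proteins IGFBP2 (8.20-fold) and IGFBP1 (4.34-fold) and the PAPP-A inhibitor STC2 (4.58-fold) were higher and IGFBP6 2.62-fold lower. Of 31 decidualization genes, which mark the progesterone-driven conversion of stroma, 4 were higher and 1 lower (8 and 4 when adjusted over the list alone; camera adjusted p = 0.392). The monoamine oxidase MAOA was 5.57-fold and GADD45A 2.24-fold higher. PRL, the classical decidual hormone, stood at 6.91 ± 0.06 (SD) in normal and 6.90 ± 0.10 in endometriotic stroma, below the array median of 7.07, and FOXO1 did not differ detectably (limma adjusted p = 0.687).

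Of 29 hypoxia and glycolysis genes, 10 were higher and none lower (12 higher and 1 lower when adjusted over the list alone; camera adjusted p = 5.7e-07, adjusted p = 0.0995 with an estimated correlation). HIF1A was 3.75-fold, PGK1 3.01-fold, BNIP3 2.97-fold and HK2 2.88-fold higher. Smooth muscle and contractile genes had 5 of 22 higher (5 when adjusted over the list alone; camera adjusted p = 0.00120, adjusted p = 0.271 with an estimated correlation), with MYH11 at 5.64-fold, ACTG2 at 3.86-fold, KCNMB1 at 3.33-fold and DES at 2.52-fold. MYH11 stood at 8.45 in endometriotic replicate 5, against a mean of 11.14 in the other 5. Of 55 cell cycle genes, CCNA2 (1.59-fold) and PLK4 (1.35-fold) were higher (1 when adjusted over the list alone; camera adjusted p = 0.000155, adjusted p = 0.570 with an estimated correlation). CDKN1A was 1.79-fold higher, the only called member of 15 cyclin-dependent kinase inhibitor and senescence genes (1 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.869).

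**Figure D3:**
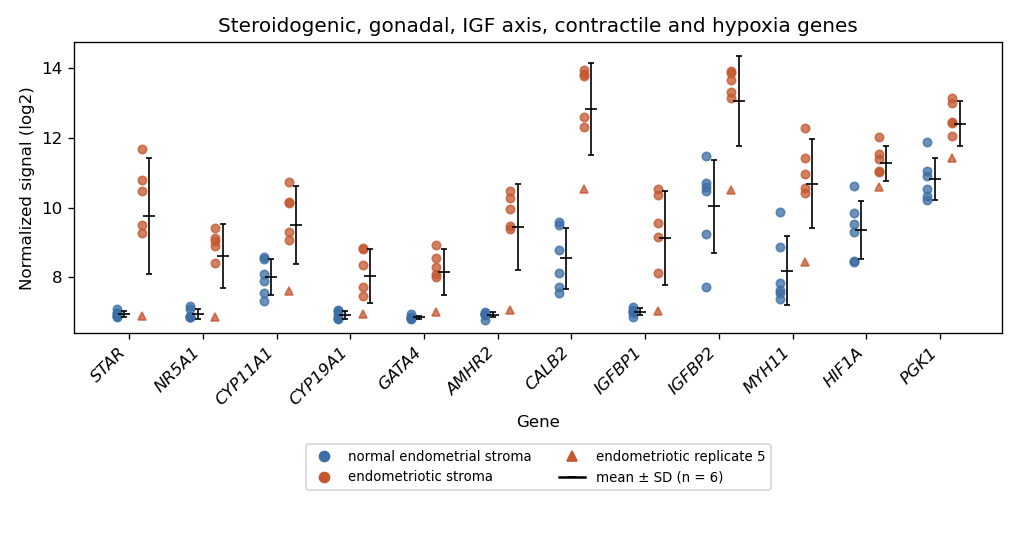
Normalized log2 signal of 12 genes higher in endometriotic stroma, with a point per array, bars for mean ± SD (6 arrays per group) and a triangle for endometriotic replicate 5. For STAR the triangle lies at 6.88, near the normal mean of 6.95, and the other 5 endometriotic arrays average 10.35.

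**Figure D4:**
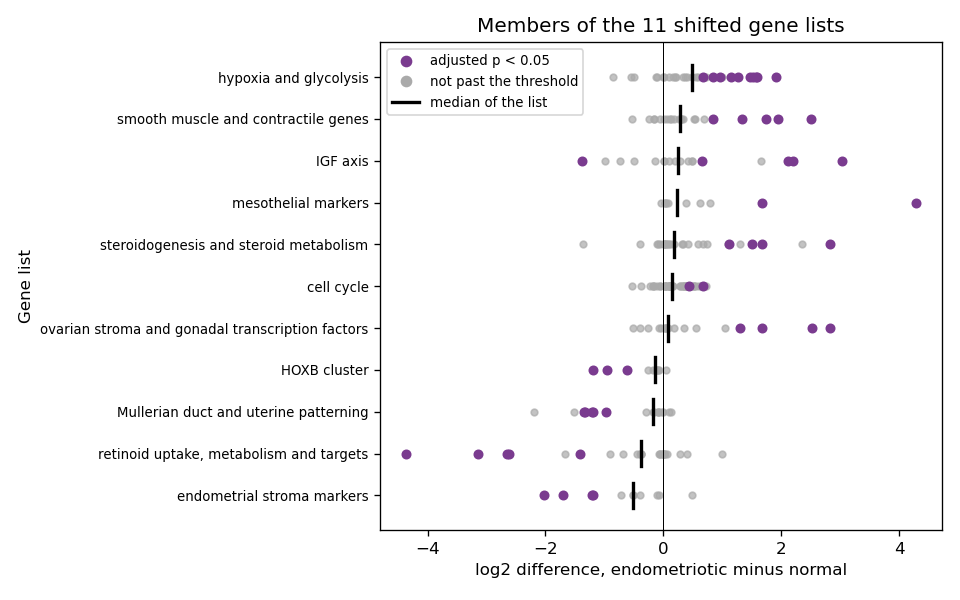
Log2 difference (endometriotic minus normal) of each measured member of the 11 lists called by camera, with the median of each list as a black bar and members past the threshold in purple. Medians run from -0.52 for endometrial stroma markers to 0.48 for hypoxia and glycolysis.

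Nuclear steroid receptors had 2 of 12 members lower, NR2F1 (2.50-fold) and the estrogen receptor ESR1 (1.56-fold; 3 when adjusted over the list alone; camera adjusted p = 0.284). PGR was 1.47-fold lower (limma adjusted p = 0.124) and ESR2 lay near the bottom of the scale in both groups (7.01 and 6.98). The prostaglandin receptors PTGER2 (2.12-fold), PTGER4 (1.94-fold) and PTGER1 (1.75-fold) were lower among 23 prostaglandin genes (5 when adjusted over the list alone; camera adjusted p = 0.141, fry adjusted p = 0.0112), while PTGS2 (limma adjusted p = 0.149) and PTGES (0.715) did not pass. Estrogen-regulated genes had RERG (2.01-fold) and MYC (1.96-fold) higher and CXCL12 (4.17-fold) lower of 20 (3 and 2 when adjusted over the list alone; camera adjusted p = 0.603), with SGK1 (1.97-fold higher, limma adjusted p = 0.0874, or 0.0170 without endometriotic replicate 5) and GREB1 (0.901) not past the threshold.

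Of 47 collagens and matrix glycoproteins, 8 were lower, with FBLN1 at 8.59-fold and COL6A3 at 3.19-fold, and 2 were higher (11 and 3 when adjusted over the list alone; camera adjusted p = 0.246, or 0.0275 without normal replicate 6; over all arrays adjusted p = 0.678 with an estimated correlation). Of 34 matrix proteases and inhibitors, 6 were lower, including MMP11 (5.36-fold), CTSK (3.48-fold), MMP3 (3.00-fold) and SERPINF1 (2.87-fold), and 1 was higher (7 and 2 when adjusted over the list alone; camera adjusted p = 0.0754). The protease list was called with the mean of a gene's probes (0.0406), with array weights (0.0414) and without endometriotic replicate 5 (0.00869), and over all arrays had adjusted p = 0.244 with an estimated correlation. MMP3 stood at 10.34 in endometriotic replicate 5, against a mean of 7.21 in the other 5. None of 23 proteoglycans was called, also when adjusted over the list alone (camera adjusted p = 0.392).

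In signalling lists, WNT genes had NKD2 (1.53-fold) and LGR4 (1.46-fold) higher and WNT2 (3.12-fold) and FZD7 (2.37-fold) lower of 45 (4 and 4 when adjusted over the list alone; camera adjusted p = 0.881). TGF-beta and BMP genes had TGFB2 (1.54-fold), BMPR1B (1.52-fold) and INHA higher and TGFB3 (2.13-fold) and CHRD (1.59-fold) lower of 40 (4 and 3 when adjusted over the list alone; camera adjusted p = 0.409). The adhesion molecule VCAM1 was 11.3-fold higher and CXCL12 lower among 43 cytokine and chemokine genes (1 and 1 when adjusted over the list alone; camera adjusted p = 0.394, or 0.00198 without normal replicate 2; over all arrays adjusted p = 0.740 with an estimated correlation). VCAM1 was 19.7-fold higher without endometriotic replicate 5, in which it stood at 8.02 against a mean of 12.85 in the other 5. Complement genes had CD59 (2.19-fold) and C3 (1.75-fold) higher and CFD (3.10-fold) and C1QTNF5 (2.35-fold) lower of 22 (5 and 2 when adjusted over the list alone; camera adjusted p = 0.284, or 0.0199 without endometriotic replicate 5, where adjusted p = 0.222 with an estimated correlation). Interferon-stimulated genes had IFITM1 and IFIT1 (1.88-fold) lower of 31 (2 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.0775). That list was called without normal replicate 1 (0.0274), 3 (0.0397), 4 (0.0305) or 6 (0.0477) or endometriotic replicate 4 (0.00714), and over all arrays had adjusted p = 0.627 with an estimated correlation. The medians of the WNT, cyclin-dependent kinase inhibitor, decidualization and heat shock lists lay just below 0 (-0.00483, -0.0385, -0.000691 and -0.00804), while their camera direction was upwards.

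FADS1 (1.76-fold lower) was the only called member of 21 cholesterol and fatty acid synthesis genes (1 when adjusted over the list alone; camera adjusted p = 0.163, or 0.0452 without normal replicate 4 and 0.0385 without endometriotic replicate 5, where adjusted p = 0.511 with an estimated correlation), and HSP90AA1 (1.65-fold higher) of 27 heat shock genes (1 when adjusted over the list alone; camera adjusted p = 0.780). No DNA methylation or Polycomb gene of 18 was called, also when adjusted over the list alone (camera adjusted p = 0.454), with limma adjusted p of 0.624 for DNMT1, 0.163 for DNMT3A and 0.296 for DNMT3B.

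Among markers of other cell types, the epithelial KRT7 (6.42-fold) and MUC1 (2.54-fold) were higher and CLDN7 (1.43-fold) lower of 15 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.165). KRT7 stood at 7.30 in endometriotic replicate 5, below the normal mean of 8.57, and was 11.1-fold higher without that array. CD14 was 6.82-fold higher, the only called leukocyte marker of 17 (2 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.165). Pericyte markers went both ways, with RGS5 6.18-fold higher and CD248 (3.25-fold), PDGFRB (3.15-fold) and ANPEP (2.56-fold) lower (2 of 10 higher and 3 lower, also when adjusted over the list alone; camera adjusted p = 0.780). None of 13 endothelial markers was called, also when adjusted over the list alone (camera adjusted p = 0.780). With an estimated correlation and all 12 arrays, only the retinoid, HOXB and uterine patterning lists held of the 11 lists called. Without endometriotic replicate 5, steroidogenesis (adjusted p = 0.0185 with an estimated correlation), endometrial stroma markers (0.0119), mesothelial markers (0.0361) and matrix proteases (0.0361) passed as well. These further calls depend on leaving out an array that was singled out from the same values. The gene count depended on single arrays, from 463 without endometriotic replicate 2 to 1398 without endometriotic replicate 5.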

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

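The tests of a wrong label, of a mixture above 10% and of values beyond the normal arrays, and the tolerance for equal shares, were chosen after the results were seen. In 248 sets of 6 values, 40 held an array far from the others of its group, where chance gives about 12.4, and 28 of the 40 were endometriotic replicate 5.

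Endometriotic replicate 5 was the array farthest from its group in distance to the rest (0.0463, next 0.0168), on the first principal component (-10.98) and on the second (31.0). It was the lowest endometriotic array for AKR1C3 (7.70), AMHR2 (7.07), BDNF (9.51), CD14 (7.67), DRC9 (8.56), HOXC6 (8.86), IGFBP2 (10.51), KRT7 (7.30), RGS5 (7.20), RNASE1 (7.32), ZFPM2 (7.57) and ZPLD1 (7.89). It was the highest for CD248 (13.68), CRABP2 (9.86), GATA2 (9.34), HOXB2 (8.43), HOXD10 (9.75), HOXD11 (9.42), HSD17B2 (9.56), MME (8.23), MMP11 (10.46), MMP3 (10.34), PTGER4 (8.18), TGFB2 (8.58) and TMEM119 (8.32). For TGFB2, the direction was away from the normal arrays. For AKR1C3 and KRT7 the array lay below every normal array (lowest 8.92 and 7.46). For CD248 and MMP3 it lay above every normal array (highest 13.21 and 9.82). For the other genes listed here it lay among the normal arrays or between the groups.

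Over genes called without it, endometriotic replicate 5 stood at 0.154 (genes higher) and 0.295 (genes lower) of the way from the normal to the endometriotic mean, inside the normal ranges of -0.0711 to 0.467 and -0.111 to 0.693 and outside those of the other endometriotic arrays (0.874 to 1.24 and 0.902 to 1.19). Normal replicate 2 alone set both upper ends, and over genes higher the next normal array stood at 0.143, below endometriotic replicate 5, so normal stroma under a wrong label may account for the array, but over genes higher its place in the normal range rests on 1 array. No normal array lay in the endometriotic range. Only 1 array was left out at a time, so these positions cannot exclude an exchange of arrays between the groups. Normal replicate 2 and endometriotic replicate 5 were each other's closest array (r = 0.968). Normal replicate 2 had a mean correlation of 0.959 both with the other normal arrays and with the endometriotic arrays. Endometriotic replicate 5 lay beyond all normal arrays towards endometriotic stroma for 31.0% of 1398 genes (14.3% by chance, 13.0% to 59.8% for single normal arrays). A mixture of both stromas stays open, because its linear shares of 0.101 and 0.377 differed by -0.276, more than the SD of 0.231 and less than the largest difference of 0.371 among the other 11 arrays; the rule as first coded, without a tolerance, had counted this value in favour of a mixture. In endometriotic replicate 5, 49 genes low in normal stroma stood at a median of 0.727% of the way from the normal to the endometriotic level. This read the values as log2 and was taken on the linear scale (quartiles -0.533% and 7.25%, 38 of 49 genes under 10%). The median argues against a share above 10% if the endometriotic cells of this array resembled those of the other arrays. Its 95% bootstrap interval (0.237 to 2.44) resampled genes within 1 array and does not measure the uncertainty of a share in the sample. The SD of dim probes was 0.119, inside the range of the other arrays (0.105 to 0.122), which gives no sign of added noise in dim probes. Quantile normalization and the compression of low signals limit this SD on any array. It therefore cannot decide whether noise in brighter probes plays a part. A lesion whose stroma resembles normal stroma was not tested and also stays open.

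Among normal arrays, replicate 1 was highest for CD248 (13.21) and EMX2 (10.84), and replicate 2 was lowest for ALDH1A1 (11.36) and highest for C3 (7.64), ZFPM2 (8.65) and ZPLD1 (7.51). Replicate 3 was lowest for WT1 (8.19). Replicate 5 was lowest for AMHR2 (6.78) and highest for TCF21 (8.39), and replicate 6 was lowest for CXADR (6.89) and DRC9 (7.35) and highest for GATA4 (6.95).

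Among 20705 probes with no single gene symbol, which entered no comparison above, 124 differed between the groups in limma with Benjamini-Hochberg adjustment, 74 higher and 50 lower in endometriotic stroma.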

How the results depend on the processing

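Cyclic loess was chosen after seeing the data. Quantile normalization and equal medians changed nothing because the deposited values were already quantile normalized, so they say nothing about stability, and a log2 offset was not run because values were already logged. No result past its threshold changed sign. The spread difference and the uncalled WNT, cyclin-dependent kinase inhibitor, endothelial and heat shock lists did under some settings. So did some uncalled named genes, among them ESR2 and WT1. The gene count of 897 became 1398 with array weights, which gave endometriotic replicate 5 the lowest weight (0.623), 891 with cyclic loess, 742 with the mean of a gene's probes and 789 with a robust variance. The exact rank-sum test called 0 genes and 0 at 2-fold, since its smallest p of 0.00216, reached by 368 genes, adjusts to 0.110, and 2809 genes had an unadjusted p under 0.05 (3498 in limma). Treat against 1.5-fold called 54 genes, against 386 changed at least 2-fold. Camera with an estimated correlation called 3 lists and fry 10, losing cell cycle (0.284) and smooth muscle (0.0823) and gaining prostaglandins (0.0112). On ranks the retinoid (adjusted p = 0.0508), ovarian stroma (0.178) and IGF axis (0.139) lists were lost, and the IGF axis also with the filter on dim genes (0.0687) and the mean of probes (0.110). Leaving out each array in turn gave 463 to 1398 genes, 282 to 587 genes at 2-fold, and a spread difference of -0.00636 (without endometriotic replicate 5, the farthest array, whose removal itself narrows the group) to 0.00206. The gene count moved over 1.5 times without normal replicate 4 (554), 5 (503) or 6 (484) and without endometriotic replicate 2 (463), 3 (518), 4 (490) or 5 (1398). Of the 897 genes, 51.2% (without endometriotic replicate 2) to 96.3% (without endometriotic replicate 5) were still called. The cause of these changes was not tested. Same-numbered arrays did not deviate together (r from -0.0952 to 0.0933, 0 of 6 matched best). Whether the numbers pair the samples stays open, because the correlation that a shared donor would give here is unknown. The replicate block gave 850 genes, 397 at 2-fold and 10 lists, and the IGF axis missed at a camera adjusted p of 0.0623. Without detection p-values, the signal over background that limits dim genes is unknown.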

Other observations

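The genes in this paragraph were chosen after their values were seen. Besides the genes named by rule, endometriotic stroma had high levels of SBSPON (15.2-fold higher, log2 difference 3.93 ± 0.71, SE), the natriuretic peptide NPPB (13.2-fold), NSG1 (10.2-fold), the elongation factor EEF1A2 (9.46-fold), the tetraspanin TSPAN8 (8.51-fold), the tight junction protein CLDN1 (6.94-fold), the transcription factor IRF8 (6.08-fold) and the apolipoprotein APOA1 (5.81-fold). Each passed the limma threshold, with adjusted p from 0.00167 for EEF1A2 to 0.0130 for APOA1. Lower in endometriotic stroma were the imprinted RNA H19 (log2 difference -3.05 ± 0.69), the procollagen processing enhancer PCOLCE (-2.88 ± 0.44), S100A4 (-2.75 ± 0.69), AEBP1 (-2.22 ± 0.36) and the mesenchymal transcription factor PRRX1 (-1.88 ± 0.43).

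IGFBP1 and PRL both mark decidualized stroma. IGFBP1 averaged 9.55 in the 5 endometriotic arrays other than replicate 5 and 7.04 in that array, while the PRL probe lay below the array median of 7.07 in both groups (6.91 in normal and 6.90 in endometriotic stroma), near the bottom of the scale, and its level cannot show a lack of change.

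CALB2 and gonadal genes were higher in endometriotic stroma, and the mesothelial test was read again without endometriotic replicate 5 after its result was seen. Only 1 of the 9 mesothelial markers other than CALB2 (ITLN1) was called, with a median log2 difference of 0.07 (SD 0.56) against 4.29 for CALB2, and by the bound set beforehand (fewer than 2 called) this argues against mesothelial cells. Without endometriotic replicate 5, 2 were called (ITLN1 and LRRN4), so that bound rested on 1 array. The mesothelial list, CALB2 included, was shifted up (camera adjusted p = 0.00153 over all arrays). Without endometriotic replicate 5 it also passed in camera with an estimated correlation (adjusted p = 0.0361). No share of mesothelial cells was estimated, and their presence stays open. Ovarian stromal cells cannot be told apart from a change in the endometriotic cells, because FOXL2 differed by 0.0707 (95% interval -0.50 to 0.64) and normal stroma already expressed it at 11.12.

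Of 462 splits of the 12 arrays into 6 and 6, 100 were drawn. Among those drawn, only the real split gave as many genes (1 of 100, with 897 against 600 for the highest other). The same held for genes at 2-fold (1 of 100, with 386 against 291). For lists, 3 of 100 gave as many (11, highest other 16). Each share was under the 0.05 level, but for the drawn splits only. The drawn splits with calls did not include the exchange of endometriotic replicate 5 with normal replicate 2, so splits not drawn may give more. Another split gave 10 lists with only 2 genes called, so the list count says little about the grouping. The split with 600 genes exchanged endometriotic replicate 5 with normal replicate 3, and the split with 16 lists exchanged it with normal replicate 4, which points to the structure of the samples around that array. No gene was called in 95 of the other splits by limma.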
